A study of Mus musculus with 4 samples.

How the data were processed

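Gene expression was measured in mouse regulatory T cells (Treg cells, CD4 T cells that express the transcription factor Foxp3 and restrain other immune cells) from the spleen of C57BL/6 animals. The series holds 4 arrays, 2 labelled wild-type and 2 labelled deficient in Foxo1 and Foxo3. Each title also numbers a pair, so that every pair holds 1 array of each genotype. The genotype field of the deficient samples names Foxo1 alone, while their titles and the series' design text name both genes; the titles were used for the groups. Total RNA was extracted with a Qiagen kit and labelled with biotin by the Affymetrix protocol, per the labels' protocols.

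The deposited values were probe-set intensities on a linear scale, made with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. MAS5 computes a background-corrected signal per probe set and scales each array. All 4 arrays had a 2% trimmed mean of 500.003, so no further scaling was applied. Median signals were 76.7 and 72.0 on the wild-type arrays and 83.4 and 72.7 on the labelled-deficient arrays. Detection calls were not analysed here, so a dim signal was not separated from absence. The number of arrays limits the precision of every value. Nothing in the labels says whether the arrays of a group came from separate animals, so p-values of single genes measure only the spread between these arrays. Sex-linked signals differed between the 2 arrays of each group, so these were not repeat arrays of a single RNA.

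The values covered 45101 probe sets, of which 64 were array controls. The platform annotation, which can be old, gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Symbols were compared with a RefSeq gene table of the GRCm38.p6 assembly, which was used for names only, and no coordinates are printed because the build behind the probe sets is not given in the sources used here. Where a probe set lies relative to the deleted part of Foxo1 or Foxo3 is likewise not given in the sources used here.

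Signals were tested as log2(signal + 17), where 17 is the 25th percentile of all values, rounded. A fold change is therefore on the log2(signal + 17) scale and understates the change of dim genes. Probe sets whose mean log2 value lay under the 40th percentile (a signal of about 40) were left out. Each gene was read from its probe set with the highest mean over the 4 arrays, which left 12115 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom, to which the shared variance model added 5.69. An exact test of 2 arrays against 2 cannot give a p under 0.333, so every p here leans on that shared variance model. Changes within each numbered pair were also counted at 2-fold without a test, and pair 2 was tested against pair 1 with genotype as a covariate.

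The titles call the number a pair, and the design text speaks of sets, which is where the pairing comes from. Over the 12115 genes, deviations from the group means correlated between arrays of the same number with a Pearson r of 0.367; this is a correlation across genes, which are not independent replicates, and rests on 2 pairs. The fit without the pair was fixed as the main one, and the fit with the pair as a block was an alternative, with its value printed beside a result where it changed the call. On simulated data with 12115 genes and 200 changed genes, repeated 10 times, the main fit recovered 63.4% of the 4-fold and 5.30% of the 2-fold changes, with 5.54% false calls. The blocked fit recovered 93.9% and 59.3% but with 13.5% false calls, above the 5% aimed at. Besides the 200 changed genes the simulated data held a list of genes shifted by less than 2-fold, whose calls did not count as false. Each fit had its own simulated data, drawn with its own variance, and only those of the blocked fit held pair differences. The rates therefore do not compare the 2 fits on the same data. Those of the main fit hold for arrays without pair differences, which these arrays have.

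Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over 32 lists. The lists covered Treg identity and activation, FoxO targets, T helper subsets, signalling, metabolism, proliferation and stress, and markers of other spleen cell types. They held 670 distinct genes, of which 549 were tested, and some genes stood in more than 1 list. camera with an estimated correlation, camera on ranks and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were alternatives. With the preset correlation, camera's p rests on the spread across genes, so a very small value does not measure agreement between arrays. The estimated correlation rests on 2 residual degrees of freedom, which the test then takes too, and with it 0 lists were called. Lists with an estimate below the preset 0.01 lost their call too, such as cytotoxic genes (-0.057, camera adjusted p = 0.191). A call lost with it therefore does not show that correlation between genes made the shift. On the simulated data the shifted list was called in 10 of 10 runs, and 0 of 310 unchanged lists were. The simulated genes varied independently of each other, so these runs do not test false calls of lists whose genes vary together. Some lists here had a higher estimated correlation, such as 0.282 for naive and lymph node homing genes.

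Named genes followed a rule: the deleted genes, the 12 higher and 12 lower genes with the largest change among those past the threshold whose groups did not overlap, and from each list up to 4 members with the smallest p. Of the members so picked that missed the threshold only Mmp9 and Tyrobp are printed. Klf2, Il7r, Ifng, Tbx21, Foxp3, Ctla4, Cd8a, Cd8b1, Fcer1g and the sex-linked genes are outside this rule and were chosen after their values were seen. The design, the lists, this rule and the alternatives were fixed before the data were examined. The alternatives were no pseudocount, a pseudocount of 76 (the median), quantile normalization, no filter, a filter at the 60th percentile, eBayes without the trend or robust, other ways to combine the probe sets of a gene, the pair as a block, and each array left out in turn.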

Results

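The data were genome-wide signals from 4 arrays of splenic Treg cells, 2 labelled wild-type and 2 labelled Foxo1/3-deficient, in 2 numbered pairs. Foxo1 and Foxo3 are transcription factors that the PI3K and AKT pathway holds out of the nucleus, and the series asks what Treg cells express without them. The 4 arrays had the same trimmed mean signal, and their log2 signals correlated across probe sets with a Pearson r between 0.960 and 0.972. The highest value joined the 2 labelled-deficient arrays, and the wild-type arrays correlated at 0.967.

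Foxo1 itself was higher, not lower, on the arrays labelled Foxo1/3-deficient. Its brightest probe set read 6823 ± 178 (SD, n = 2) there against 1819 ± 798 on the wild-type arrays, a log2 difference of 1.97 ± 0.30 (SE; limma adjusted p = 0.0209). The other measured Foxo1 probe sets went the same way, with signals of 4485 and 4015 against 1161 and 720 on one, and of 3133 and 3438 against 786 and 612 on the other. Ratios within a pair ran from 2.92 to 5.62 over these 3 probe sets. Foxo3 was lower on the same arrays, at 1366 ± 82.3 against 2256 ± 537, a log2 difference of -0.70 ± 0.24 that missed the threshold (adjusted p = 0.241). With the pair as a block the Foxo3 difference passed over genes (adjusted p = 0.0127) but not when every probe set was tested (0.0813). A second Foxo3 probe set read 554 and 521 against 861 and 1001 (adjusted p = 0.0704 with the block over every probe set). The Foxo1 difference held without any 1 array, but its adjusted p was 0.0685 without the filter on dim probe sets and 0.0788 without the intensity trend. The Foxo1 signal thus went against the label on both arrays, and every direction given from here on is that of the arrays as labelled. A probe set outside the deleted part of a gene would not show its deletion, and the position of these probe sets relative to that part is not given in the sources used here.

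**Figure D1:**
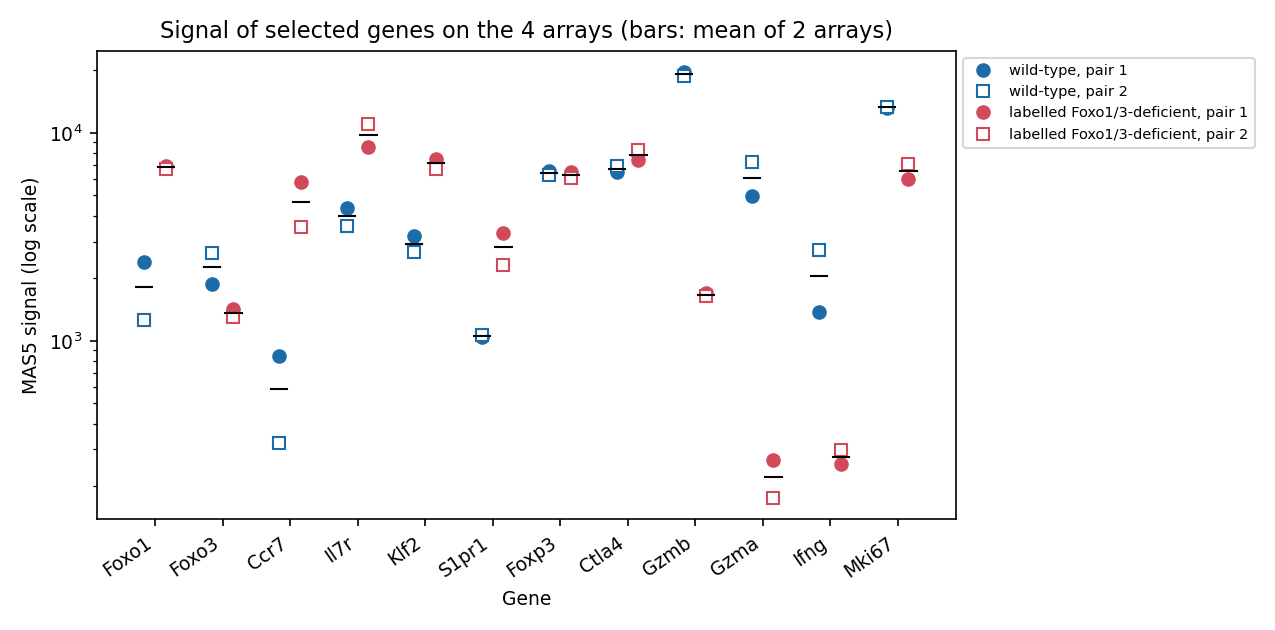
MAS5 signal (log axis) of 12 genes on the 4 arrays; circles are pair 1, squares pair 2, blue the wild-type arrays, red the arrays labelled Foxo1/3-deficient, and each black bar is the mean of 2 arrays. Foxo1 read 6823 on average on the labelled-deficient arrays and 1819 on the wild-type arrays, while Gzmb read 1668 and 19194.

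The comparison of genotypes asked which transcripts differ between Treg cells labelled Foxo1/3-deficient and wild-type. Genes of resting, recirculating T cells were higher on the labelled-deficient arrays, and genes of cytotoxic and activated cells were lower. Camera called these lists only with its preset correlation (naive and homing adjusted p = 0.212, cytotoxic 0.191 and effector Treg 0.191 with an estimated correlation), and fry did not call the naive and homing list (0.0558). For cytotoxic genes the estimate (-0.057) lay below the preset, so that loss cannot be put down to a higher correlation. On the log2(signal + 17) scale the rise ranked highest was that of St8sia6, which encodes a sialyltransferase, from 175 ± 3.81 to 6355 ± 138 (SD, n = 2), a 33.3-fold change (log2 5.06 ± 0.22, adjusted p = 0.000282). Dapl1 rose 28.8-fold, Gsta4 (a glutathione S-transferase) 27.2-fold and Prg4 (lubricin) 25.3-fold, all from mean signals under 50 on the wild-type arrays; their rank against St8sia6 was set by the pseudocount, since without it Dapl1 stood at log2 6.88, Gsta4 at 5.96, Prg4 at 5.32 and St8sia6 at 5.19. Igf1r, the receptor for insulin-like growth factor, rose 10.6-fold, and Ccr7, the chemokine receptor that guides T cells into lymph nodes, 8.38-fold. Gbp2b (9.70-fold), Tdrp (8.93-fold), Gm11346 (8.62-fold), Ms4a6c (8.51-fold), Cnga1 (7.85-fold) and Myo6, an unconventional myosin (7.67-fold), completed the 12 rises named by size on that scale. A second probe set of Ms4a6c did not show the rise (log2 -0.17).

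On the same scale the fall ranked highest was that of Gzma, a serine protease of cytotoxic granules, from 6100 ± 1617 to 221 ± 64.7 (SD, n = 2), 25.7-fold lower (log2 -4.68 ± 0.30, adjusted p = 0.00152). Gzmb, another granule protease, fell from 19194 ± 601 to 1668 ± 31.5, 11.4-fold lower. Nxnl2 (14.1-fold), the small GTPase gene Rasd2 (12.6-fold), 5830411N06Rik (11.1-fold) and Ltbp1, which binds latent TGF-beta (10.7-fold), fell too. So did the chemokine gene Ccl3 (10.1-fold), Scin (10.1-fold), the interleukin-1 receptor gene Il1r1 (9.57-fold), Lipm (9.55-fold), Il17re (9.36-fold) and Havcr2, which encodes the inhibitory receptor TIM-3 (8.94-fold). This order also depends on the pseudocount: without it Nxnl2 stood at log2 -5.19, Ltbp1 at -5.11 and Gzma at -4.79, and Nxnl2, Rasd2, Ltbp1, Ccl3 and Il1r1 had mean signals under 17 on the labelled-deficient arrays (Ccl3 stood at -4.54 and Il1r1 at -4.41 without it). Rasd2 went from log2 -3.66 to -0.60 without a pseudocount (limma adjusted p = 0.745), where the other of its 2 kept probe sets was read. The first of these read 294 and 302 on the wild-type and 9.17 and 6.67 on the labelled-deficient arrays, a fall that the pseudocount makes smaller. Rasd2 stood at -0.46 on its first-listed probe set (0.764). On theirs, Igf1r shrank from 3.40 to 1.34 (0.103) and Il17re from -3.23 to -1.30 (0.151).

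In all, 147 genes were higher and 164 lower on the labelled-deficient arrays among 12115 tested (limma, adjusted p under 0.05), and 718 and 854 at an unadjusted p under 0.05. For each of the 311 genes both arrays of one label lay beyond both of the other. The same was true of 4975 of all genes (41.1%), where chance gives 33.3%. With the pair as a block 634 were higher and 770 lower, including all of the 147 and 164. The counts fell to 67 and 82 without labelled-deficient replicate 1 and to 72 and 104 without labelled-deficient replicate 2, and rose to 278 and 266 without wild-type replicate 1; without the filter they were 45 and 44, and without the intensity trend 57 and 54.

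**Figure D2:**
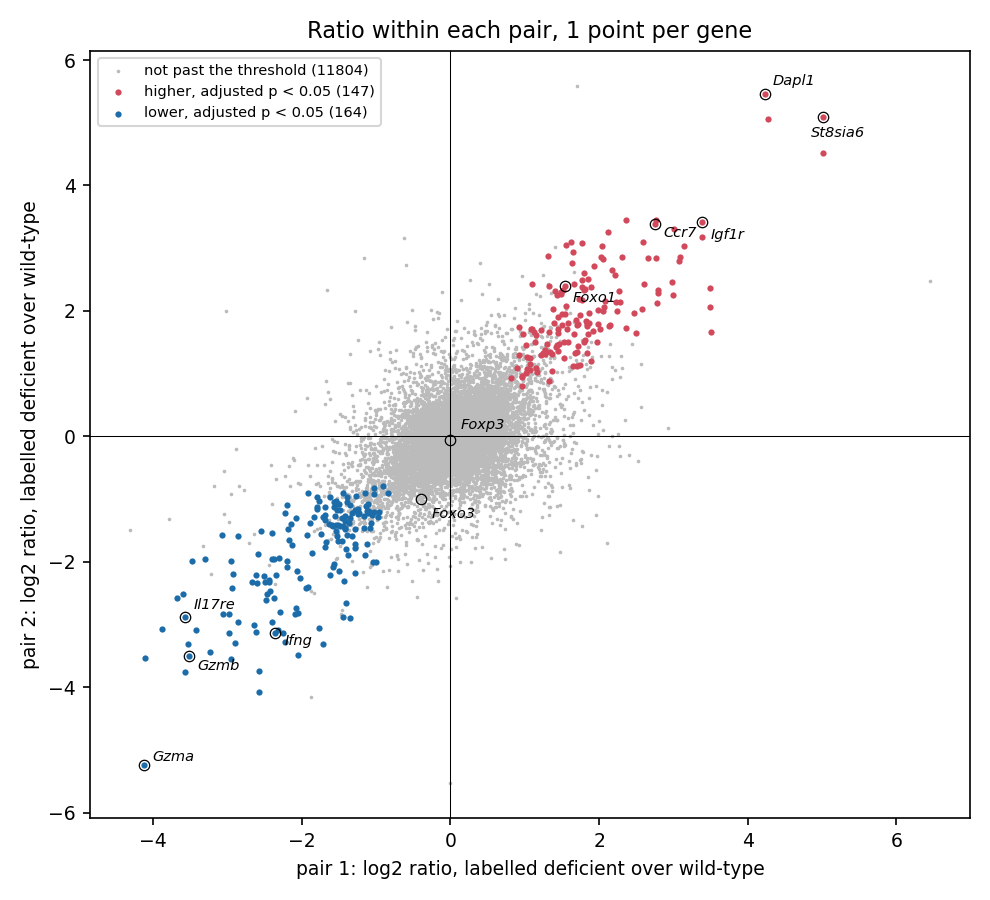
Log2 ratio of the array labelled Foxo1/3-deficient over the wild-type array within pair 1 (x axis) and pair 2 (y axis), 1 point per gene for 12115 genes; red points are the 147 genes called higher, blue the 164 called lower, and circled genes are named. St8sia6, Dapl1, Ccr7, Igf1r and Foxo1 lie above 0 in both pairs, Gzma, Gzmb, Il17re and Ifng below 0 in both, and Foxp3 near 0.

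Within the numbered pairs, 250 genes were at least 2-fold higher and 281 at least 2-fold lower on the labelled-deficient array in both pairs, among them Ccr7, Gzmb and Gzma. Between the pairs, at the same size, 47 genes were higher and 107 lower in pair 2 than in pair 1 in both genotypes. Those pair counts became 28 and 41 with the median as pseudocount, 30 and 62 with the filter at the 60th percentile, 77 and 155 without the filter and 138 and 253 over every probe set. The log2 ratios of the 2 pairs correlated across genes with a Pearson r of 0.549, and 20 genes moved at least 2-fold in opposite directions; that number ran from 4 (the median as pseudocount, or the filter at the 60th percentile) to 53 without a pseudocount, 84 over every probe set and 101 without the filter. No test was applied to these counts.

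Genes of naive and lymph node homing T cells were higher as a group on the labelled-deficient arrays. Of 19 members tested 15 rose and 0 fell, with a median log2 change of 1.80, and 19 rose when adjusted over the list alone; 19 also rose with the pair as a block. Besides Dapl1 and Ccr7, Igfbp4 rose 5.42-fold, Actn1 4.37-fold and the transcription factor gene Klf3 2.92-fold. Klf2, a transcription factor of T cell quiescence, rose from 2920 ± 360 to 7128 ± 553 (SD, n = 2), Il7r, the receptor for interleukin-7, from 3966 ± 559 to 9805 ± 1753, and S1pr1, the receptor for lymphoid exit, 2.60-fold. Camera called the list (adjusted p = 5.36e-27), but not with an estimated correlation (adjusted p = 0.212 with an estimated correlation), and fry gave an adjusted p of 0.0558. Without labelled-deficient replicate 1, S1pr1 and Klf2 missed the threshold (adjusted p = 0.195 and 0.0893), as Il7r did without labelled-deficient replicate 2 (0.0941).

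FoxO stress and cell cycle target genes moved both ways, with more rises than falls. Of 34 tested 6 rose and 1 fell, with a median log2 change of 0.41, and 9 rose and 6 fell when adjusted over the list alone. The rises included Pik3ip1, an inhibitor of PI3K (4.21-fold), Sesn1, a stress-response gene (3.89-fold), and Insr, the insulin receptor (3.62-fold). Cdkn1a, a cyclin-dependent kinase inhibitor, was the member that fell (3.66-fold lower). With the pair as a block 10 rose and 6 fell. Camera gave an adjusted p of 0.00400, with 0.261 as the adjusted p with an estimated correlation, and fry called the list (adjusted p = 0.00940). Insr missed the threshold without either labelled-deficient replicate (adjusted p = 0.0521 and 0.0907), and Cdkn1a without labelled-deficient replicate 2 (0.0838), and Sesn1 on its first-listed probe set (0.0724).

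The transcripts that define Treg cells did not shift in 1 direction as a group, though single members moved both ways. Foxp3 read 6280 ± 317 on the labelled-deficient and 6412 ± 180 (SD, n = 2) on the wild-type arrays, a log2 difference of -0.03 ± 0.17 (adjusted p = 0.987) whose sign turned under quantile normalization. Ctla4, an inhibitory receptor of Treg cells, differed by 0.21 ± 0.18 (adjusted p = 0.753). Of 31 Treg signature genes tested 6 rose and 3 fell, with 7 and 5 when adjusted over the list alone and 9 and 5 with the pair as a block. The rises included Plagl1 (7.63-fold), the receptor gene Gpr83 (6.72-fold) and Izumo1r, which encodes folate receptor 4 (2.15-fold), and the falls Gzmb and Klrg1, a receptor of terminally differentiated cells (4.27-fold lower). The median log2 change was -0.03 while the mean was 0.11 and the test pointed up (adjusted p = 0.417). Plagl1 missed the threshold on its first-listed probe set (log2 0.64, adjusted p = 0.602), and Izumo1r without either labelled-deficient replicate (0.223 and 0.0746).

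Genes of Th1 cells, the helper cells that make interferon-gamma, and cytotoxic genes were lower on the labelled-deficient arrays. Of 17 Th1 genes tested 8 fell and 0 rose, with a median log2 change of -1.32, and 15 fell both when adjusted over the list alone and with the pair as a block. Ifng itself went from 2060 ± 959 to 276 ± 30.8 (SD, n = 2) and Tbx21, the Th1 transcription factor gene, from 2180 ± 310 to 470 ± 29.1. Nkg7 (7.31-fold), Ccl5 (6.40-fold), Il18rap (4.86-fold) and the chemokine receptor gene Cxcr3 (2.76-fold) fell with them. Of 18 cytotoxic genes 7 fell and 0 rose, with a median of -1.26, and 13 fell adjusted over the list alone and with the block. Camera called both lists (adjusted p = 3.36e-18 and 2.42e-16), with 0.191 for each as the adjusted p with an estimated correlation, and fry called both (0.0245 and 0.00114). The 2 lists share 2 genes.

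Effector Treg genes, which mark activated Treg cells, and Th17 genes were also lower. Of 31 effector Treg genes tested 13 fell and 0 rose (median log2 -0.90), and 19 fell and 2 rose when adjusted over the list alone. Besides Gzmb, Havcr2, Klrg1 and Ccl5, they included the calcium-binding protein gene S100a4 (3.11-fold lower), the inhibitory receptor gene Pdcd1 (2.94-fold lower) and Prdm1, which encodes Blimp-1 (2.66-fold lower). With the block 20 fell and 2 rose. Of 13 Th17 genes 4 fell and 0 rose (median -0.83, 6 falls adjusted over the list alone, and 7 falls and 1 rise with the block): Il1r1, Il17re, the cytokine gene Csf2 (7.09-fold lower) and Ahr, the aryl hydrocarbon receptor (3.03-fold lower). Of the 13, 12 lay below 0, but Il17a and Ccr6 only by log2 -0.02 and -0.07, and Irf4 stood at 0.61. Il17a was dim, at 51.6 on the wild-type and 50.6 on the labelled-deficient arrays. The effector Treg and Th17 lists share 3 genes, so their falls are not separate results. Camera gave adjusted p values of 2.49e-15 for effector Treg and 7.36e-07 for Th17 genes. With an estimated correlation its adjusted p values were 0.191 and 0.198, and fry called both lists (0.0162 and 0.0148). Pdcd1, Prdm1 and Ahr missed the threshold without labelled-deficient replicate 1 (adjusted p = 0.0511, 0.144 and 0.0745), and Ahr on the mean of its probe sets (0.0770).

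Genes of mitosis and DNA replication were lower on the labelled-deficient arrays. All of the 39 members tested had a log2 change below 0, with a median of -1.10; 11 fell past the threshold and 0 rose, and 37 fell when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, was 2.84-fold lower, the mitotic kinase genes Aurkb and Cdk1 were 2.79-fold and 2.60-fold lower, and Mki67, which encodes the proliferation marker Ki-67, went from 13250 ± 10.3 to 6528 ± 780 (SD, n = 2). With the block 34 fell. Camera gave an adjusted p of 1.12e-28, with 0.191 as the adjusted p with an estimated correlation, and fry called the list (0.0245). Without labelled-deficient replicate 1, Rrm2, Aurkb, Cdk1 and Mki67 missed the threshold (adjusted p = 0.0739, 0.0728, 0.0716 and 0.140), as Aurkb and Cdk1 did without labelled-deficient replicate 2 (0.0775 and 0.0878).

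Interferon response genes were lower by less. Of 31 tested 1 fell, Iigp1, an interferon-inducible GTPase (2.52-fold lower), and 0 rose; the median log2 change was -0.30, 8 fell when adjusted over the list alone and 13 with the block. Camera gave an adjusted p of 2.30e-07, with 0.539 as the adjusted p with an estimated correlation, and fry did not call the list (0.274). Iigp1 missed the threshold without either labelled-deficient replicate (adjusted p = 0.0603 and 0.0835) and on its first-listed probe set (0.0603).

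**Figure D3:**
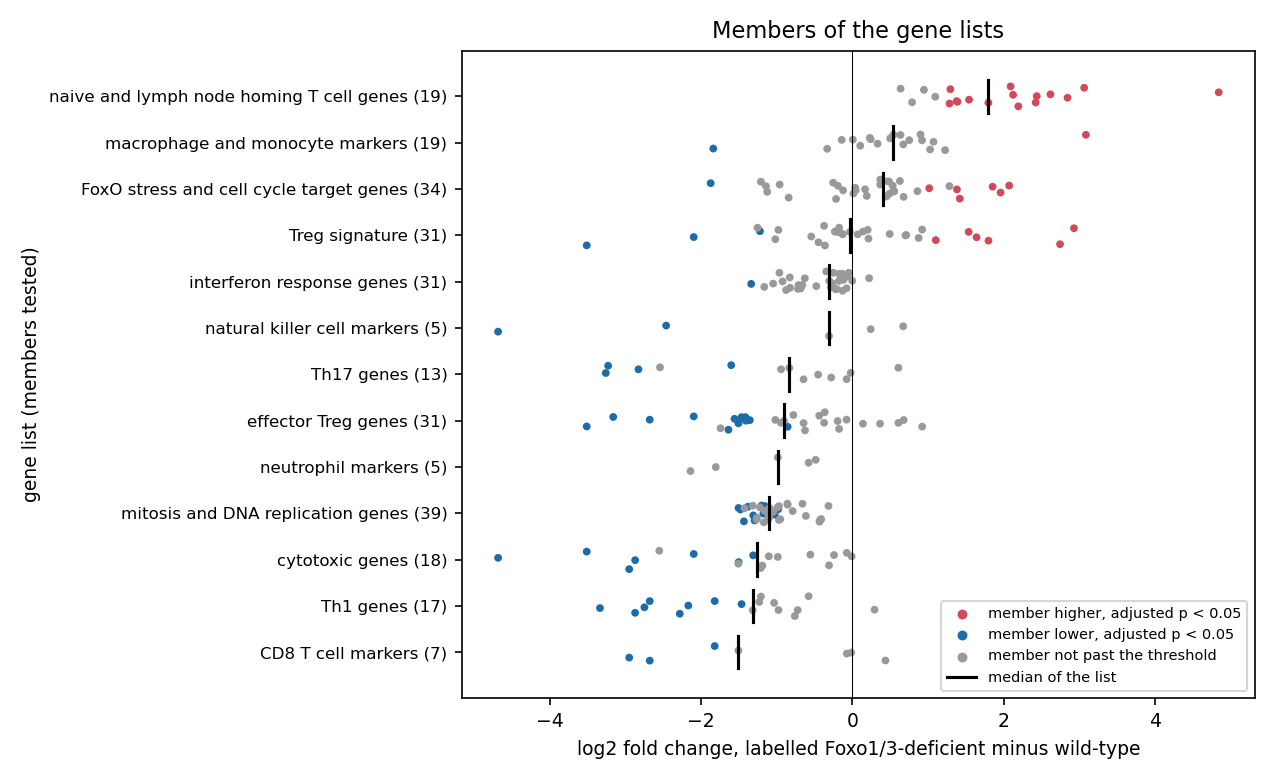
Log2 fold change (x axis, labelled Foxo1/3-deficient minus wild-type) of each tested member of the 12 lists that camera called and of the Treg signature; red and blue points passed the threshold for single genes, grey did not, and black bars are list medians. The medians run from -1.51 for CD8 T cell markers to 1.80 for naive and lymph node homing genes.

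Markers of other spleen cell types were measured to see which cells besides Treg cells the RNA held. CD8 T cell markers had a median log2 change of -1.51, and 3 of 7 fell: Klrc1 (7.72-fold lower), Ccl5 and the transcription factor gene Eomes (3.53-fold lower). Cd8a and Cd8b1, the receptor genes of CD8 T cells, differed by only -0.01 ± 0.36 and 0.44 ± 0.33, and the highest signal of either on the 4 arrays was 444. Only 5 of 11 natural killer cell markers and 5 of 12 neutrophil markers named on the array passed the filter on dim probe sets. The natural killer cell markers had a median of -0.31, and 2 of 5 fell: Gzma and Cd160 (5.50-fold lower). Prf1 stood at log2 -0.31 ± 0.38. Tyrobp and Fcer1g, adaptor genes of natural killer and myeloid cells, differed by 0.67 ± 0.48 and 0.24 ± 0.54, and Tyrobp passed without wild-type replicate 1 (adjusted p = 0.0165). Neutrophil markers had a median of -0.98 with 0 of 5 past the threshold by limma (1 adjusted over the list alone, 2 with the block). The protease gene Mmp9 stood at log2 -2.14 ± 0.61 (adjusted p = 0.141, but 0.000341 with the block, 0.0394 without wild-type replicate 1 and 0.00379 without labelled-deficient replicate 2), and between -3.19 and -1.09 when 1 array was left out. Macrophage and monocyte markers had a median of 0.54, and of 19 Ms4a6c rose and Ifitm3 fell (3.57-fold lower), with 6 rises and 1 fall with the block. Adjusted over the list alone, 4 CD8 T cell and 2 natural killer cell markers fell, and 3 macrophage markers rose and 1 fell. The CD8 T cell list shares 3 genes with the cytotoxic list and 2 with the Th1 list. The natural killer list shares 2 with the cytotoxic list and 2 with the macrophage list. The falls of the CD8 T cell and natural killer lists are therefore not separate from those of the cytotoxic and Th1 lists.

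Camera called these 4 marker lists (adjusted p = 0.000395, 0.0176, 0.0206 and 0.00114 in the order CD8 T cell, natural killer, neutrophil, macrophage), and none held with an estimated correlation (adjusted p = 0.260, 0.382, 0.454 and 0.539 with an estimated correlation) or under fry. Without wild-type replicate 1 the natural killer and neutrophil lists were not called (adjusted p = 0.167 and 0.205), nor was the macrophage list without wild-type replicate 2 (0.137) or on the first-listed probe set (0.0596), the neutrophil list without the filter (0.115), or the CD8 T cell and natural killer lists with ranks (0.0752 and 0.431). B cell markers had a median of 0.26 and were not called (adjusted p = 0.238), but they stood apart by array: without wild-type replicate 1 the median was 0.95 (adjusted p = 2.67e-07) and without wild-type replicate 2 it was -0.42 (0.0172). Plasma cell markers (median 0.01, with a test that pointed down), dendritic cell markers (-0.02, with a test that pointed up), red cell precursor markers (0.04) and stromal and endothelial markers (0.28) were not called (adjusted p from 0.361 to 0.944). Their members past the threshold were Prdm1 and the dendritic cell transcription factor gene Irf8 (2.44-fold lower), and Gata1, a red cell transcription factor gene (3.31-fold higher). Adjusted over the list alone, 1 plasma cell marker and 1 dendritic cell marker fell, and 1 dendritic and 1 red cell marker rose; the block gave the same counts, and 1 rise and 1 fall among B cell markers.

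Among the remaining lists, single members moved while the list was not called. Of TGF-beta pathway genes (median 0.02), Id3, an inhibitor of helix-loop-helix factors, rose 7.19-fold, and Id2 and Tgfb3 fell (2.64-fold and 3.32-fold lower). Of follicular helper genes (median 0.14) Slamf6 rose from 591 ± 61.1 to 2413 ± 197 (SD, n = 2) along with Izumo1r, and Pdcd1 fell. Of chemokine receptor and integrin genes (median -0.17) the integrin gene Itga6 rose 2.77-fold with Ccr7 and S1pr1, and Cxcr3 fell. The survival gene Bcl2 rose 4.27-fold in the BCL2 family list (median -0.16, with a test that pointed up) and in the IL-2 and STAT5 list (-0.07). Pik3cd, a catalytic subunit of PI3K, rose 2.74-fold with Pik3ip1 among PI3K and AKT genes (0.22). Penk fell 5.71-fold among Th2 genes (-0.37), the asparagine synthetase gene Asns 2.60-fold among mTORC1 and amino acid response genes (-0.21), and Nr4a2 4.36-fold among immediate early genes (-0.02). Adjusted over the list alone, members rose and fell as follows: TGF-beta 2 and 2, follicular helper 4 and 3, chemokine receptor 3 and 2, BCL2 family 2 and 0, IL-2 1 and 3, PI3K 3 and 0, Th2 0 and 2, amino acid response 0 and 1, immediate early 0 and 1. With the pair as a block the counts were 6 and 4, 5 and 4, 6 and 4, 2 and 1, 4 and 3, 3 and 1, 0 and 2, 1 and 3, and 4 and 4.

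Glycolysis (median -0.19), oxidative phosphorylation (-0.13), cholesterol synthesis (-0.02), ribosomal protein (0.01) and heat shock genes (-0.08) had 0 members past the threshold by limma; over the list alone 1 glycolysis and 1 heat shock gene fell, and with the block 2 glycolysis genes fell and 1 rose and 2 heat shock genes fell. Adjusted p values of the 20 lists that camera did not call ran from 0.0611 to 0.944. Glycolysis genes passed on the mean of a gene's probe sets (adjusted p = 0.0465), on the first-listed probe set (0.0360) and without the filter (0.0468), ribosomal protein genes after quantile normalization (0.0199) and oxidative phosphorylation genes with ranks (0.0150). Without wild-type replicate 1 the Th2 (0.0328), PI3K (0.0279) and ribosomal lists (0.020) passed, without labelled-deficient replicate 1 the Th2 list (0.0322), and without wild-type replicate 2 oxidative phosphorylation (0.0433). Of the single genes just named, Asns, Tgfb3, Nr4a2 and Gata1 missed the threshold without either labelled-deficient replicate and without wild-type replicate 2 (adjusted p from 0.0547 to 0.189), Pik3cd and Ifitm3 without either labelled-deficient replicate (0.0527 to 0.112), Id2 and Irf8 without replicate 1 of that group (0.0664 and 0.176), and Bcl2 and Eomes without its replicate 2 (0.0607 and 0.0544). On its first-listed probe set Nr4a2 turned to log2 0.25, and Pik3cd, Id2, Bcl2, Tgfb3 and Gata1 missed the threshold (adjusted p = 0.987, 0.230, 0.0545, 0.0527 and 0.0508). Nr4a2 and Pik3cd also missed it on the mean of their probe sets (0.253 and 0.0815), Nr4a2, Tgfb3 and Gata1 without a pseudocount (0.0501 to 0.0523), and Nr4a2 and Tgfb3 with the median as pseudocount (0.0513 and 0.0502).

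Many of the genes named were called only with the filter and the intensity trend. Foxo1, Ccr7, Klf2, Il7r, S1pr1, Insr, Cdkn1a, Penk, Ahr, Izumo1r, Aurkb, Mki67, Rrm2, Bcl2, Nr4a2, Id2, Tgfb3, Cxcr3, Iigp1, Asns, Pik3cd, Prdm1, Eomes, Ifitm3, Irf8 and Gata1 missed the threshold without the filter and also without the trend. Scin missed it without the filter (adjusted p = 0.0685), and Cdk1, Itga6, Sesn1, S100a4, Klf3 and Pdcd1 without the trend (0.0520 to 0.0670). Ccr7 had an adjusted p of 0.0608 without the filter and 0.0624 without the trend; over all of these genes the values ran from 0.0509 to 0.147 and from 0.0520 to 0.130.

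The pairs themselves differed. Y-linked genes read high in pair 2 and near the floor in pair 1: Eif2s3y read 10.3 and 4.01 on the arrays of pair 1, and 5396 (wild-type) and 6414 (labelled-deficient) in pair 2. Xist, the RNA of the inactive X chromosome, read 12934 and 10387 in pair 1, 1909 on the wild-type and 17.2 on the labelled-deficient array of pair 2. With genotype as a covariate 359 genes were higher and 462 lower in pair 2 (limma, adjusted p under 0.05), against 3 and 0 without the intensity trend (652 and 1168 at an unadjusted p under 0.05) and 148 and 198 without the filter. The same model, with genotype as the tested term, gave 634 and 770, so these counts are not to be set against 147 and 164. On simulated data the genotype calls of that model were 13.5% false. B cell markers were lower in pair 2 (median log2 -0.79, camera adjusted p = 1.18e-06), as were macrophage markers (-0.47, adjusted p = 0.00437), interferon response genes (-0.30, 0.000886) and naive and lymph node homing genes (-0.24, 0.00360), while Th1 genes were higher (0.15, 0.0234); these 5 lists were the ones called. The pair shift was tested with the preset correlation only.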

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

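All tests of an explanation in this part were chosen after the results were seen.

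The Foxo1 signal went against the label, with a log2 difference of 1.97 (labelled-deficient minus wild-type), and Ccr7, Il7r, Klf2 and S1pr1, genes whose expression Foxo1 is known to favour in T cells, stood at a mean of 1.76 ± 0.14 (SE), at 1.65 in pair 1 and 1.86 in pair 2. Labels exchanged within both pairs would give these values. Foxo1 was fixed beforehand, but the 4 other genes and the test were chosen after their values were seen, so the test does not decide. Among lists fixed beforehand, all 19 naive and homing genes, which include Ccr7, were higher in both pairs (median 1.80). FoxO stress and cell cycle target genes were mixed, with 24 above 0 and 10 below. That list was called higher by camera (adjusted p = 0.00400, but 0.261 with an estimated correlation) and by fry (0.00940). All 5 genes missed the threshold without the filter, at the same log2 differences. RNA degradation stays open too. The 3' to 5' signal ratios separated the groups for 0 of 2 control genes (Gapdh and Actb). That is common by chance with 2 arrays against 2. An exchange cannot be told apart from right labels with RNA of the deleted alleles still read by the probe sets, which the Foxo3 difference of -0.70 leaves open because it missed the threshold without the pair as a block and the position of the probe sets is not known here. That alone would not account for the rise of Ccr7, Il7r, Klf2 and S1pr1. An exchange would leave the Foxo3 signal higher in the cells that lack it. That Foxo3 difference missed the threshold in the main fit, and the unknown position applies to its probe sets too, so it does not decide against an exchange. An effect of the deletion itself on these genes stays open and untested, and no array was moved to another group.

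Cytotoxic genes were lower on the labelled-deficient arrays, with a list median of -1.26. CD8 T cells among the wild-type cells are argued against as the source: Cd8a and Cd8b1 stood at a mean of 0.21 ± 0.24 (SE), and at -0.08 at the lowest without 1 array, more than 2 SE above the list's median; the series describes the cells as CD4 and Foxp3 positive, and how they were isolated is not given in the sources used here. A sex difference between the arrays is argued against by pair 1, where both arrays showed Xist and no Y-linked signal and the median was still -1.08 (-1.37 in pair 2). Natural killer cells stay open: Tyrobp and Fcer1g stood at a mean of 0.46 ± 0.36 (lowest -0.40 without 1 array), but macrophages carry these genes too, so more macrophages would hide a loss; camera called the macrophage list higher with its preset correlation and not with an estimated one (adjusted p = 0.539). A difference in the share of activated or dividing Treg cells, or the genotype, stays open and was not tested.

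Xist was read at 1909 on the wild-type array of pair 2, beside Y-linked signal; what drew attention was this sex-linked signal, which no genotype result rests on. Over 3 Xist probe sets that array reached a median of 16.4% of pair 1 (5.73% to 39.8%), on each above the other pair 2 array and below both arrays of pair 1, as RNA of both sexes in that sample would give, though that test too was chosen on these values. Xist made by Y-bearing cells cannot be told apart from it: Y-linked genes reached a median of 84.1% of the other pair 2 array over the brightest probe sets of Eif2s3y, Kdm5d and Uty (lowest 72.2%), and no replicate gives the spread of that share. Their dimmer probe sets ran from 7.68% (Uty) to 170% (Kdm5d). No other biological explanation was tested. Without this array 175 genes were higher and 176 lower on the labelled-deficient arrays.

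The dap spike-in control, an RNA added to every sample and left out of the comparisons, differed 5.02-fold between the arrays with the highest and the lowest signal (8052 and 1603, the labelled-deficient arrays of pair 2 and pair 1). Among 4786 tested probe sets without a single gene name, 32 passed the threshold, 16 higher and 16 lower, and they are in no comparison of genes. The 20 genes that moved at least 2-fold in opposite directions in the 2 pairs (4 to 101 over the alternatives) included Ccl9 (log2 -3.02 in pair 1 and 2.00 in pair 2), named after its values were seen; the difference between the pairs was not tested.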

How the results depend on the processing

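All alternatives were planned. The genotype counts of 147 higher and 164 lower became 45 and 44 without the filter, where 18193 genes were tested, 57 and 54 without the intensity trend, and 634 and 770 with the pair as a replicate block; leaving out 1 array gave 67 to 278 and 82 to 266. The cause was not tested beyond the number of genes and arrays. Genes 2-fold changed in both pairs became 513 and 429 when every probe set was counted. The pair counts of 359 and 462 became 148 and 198 without the filter and 3 and 0 without the trend. Lists called higher (3) became 0 with an estimated correlation and 1 with fry, and 2 to 6 without 1 array; lists called lower (9) became 0 and 5. The Foxo1 difference (1.97) missed the threshold without the filter and without the trend, and the Foxo3 difference (-0.70) passed it with the block. The other settings kept these counts within 1.5 times.

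Besides Foxo1, 70 named genes were called; 44 were still called without the filter, 39 without the trend, 57 on the first-listed unambiguous probe set, 50 and 55 without labelled-deficient replicate 1 and 2, 66 without wild-type replicate 2 and 70 with the block, with quantile normalization and without wild-type replicate 1. Ms4a6c (-0.17) and Nr4a2 (0.25) changed sign on the first-listed probe set. Of the values near 0, Foxp3 turned to 0.024 with quantile normalization and Cd8a to 0.074 on the mean of its probe sets. Leaving out 1 array moved Foxp3 between -0.082 and 0.021, Cd8a between -0.33 and 0.30, Tyrobp between -0.15 and 1.498, Fcer1g between -0.65 and 1.14 and the B cell list between -0.42 and 0.95. Of the genes printed the block changed the call of Foxo3 and Mmp9 only, and of no list; of 66 genes that the naming rule picks but that missed the threshold and are not printed, 28 passed with it. With 1 array in a group, that array was assumed to vary like the other group. Dim genes are limited by the pseudocount, since signals near 17 carry little of any change.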
